A study of Mus musculus with 6 samples.

How the data were processed

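RNA was measured in 6 subcutaneous tumours grown in C57BL/6J mice from KPC1242 cells, a mouse pancreatic ductal adenocarcinoma line. Each mouse had received 250000 cells. Folinic acid (FA), a reduced form of folate, or phosphate-buffered saline (PBS) was given once a day by gavage at 2 mg FA per dose from day 8 to day 12, and tumours were taken on day 14. Per the labels' protocols, RNA with an integrity number above 8 was used, 4 µg went into each stranded total RNA library, and 12 PCR cycles were run. There were 3 FA and 3 PBS tumours, each with 1 library. The labels do not say in so many words that each tumour came from a separate mouse. The p-values of single genes therefore measure the spread between these 6 tumours.

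The authors deposited 1 table of TPM (a transcript abundance scaled by transcript length and to the same total in every library) for 55357 Ensembl genes in the 6 tumours. The submitters' processing notes name FastQC, STAR, featureCounts and RSEM, without versions or roles. The genome build and the gene annotation are not given in the sources used here, so no coordinates are printed. Gene symbols are those paired with the identifiers in the table. Columns were matched to tumours through the sample descriptions. Those descriptions share 1 prefix in all FA tumours and another in all PBS tumours, so whatever the prefix marks cannot be separated from treatment. Each column summed to the same total, as TPM does, and TPM keeps no depth. The number of reads behind a value is therefore unknown, and no counting interval or detection floor is given. Between 23858 and 25669 genes were above 0 in a tumour.

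Values were analysed as log2(TPM + 1) in R 4.3.3 with limma 3.58.1, on the 15023 genes with a mean of at least 1 TPM over the 6 tumours. The pseudocount of 1 makes a log2 difference smaller than the true one for genes of few TPM. A linear model of FA against PBS with no covariate was fitted to each gene, with an empirical Bayes spread that follows the mean, and two-sided p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Errors beside TPM are SD over 3 tumours, errors beside log2 differences are standard errors, and intervals are at 95%. A count test was not used because TPM is not a count.

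The test, the filter, 39 gene lists and the rule for named genes were fixed before the data were examined. The lists cover lymphocyte, myeloid and stromal cell types, interferon responses, antigen presentation, cytokines, extracellular matrix, tumour epithelium, proliferation, folate and nucleotide metabolism, stress, hypoxia, and tissues that a subcutaneous tumour could carry. All 620 of their symbols were in the table, and few genes belonged to more than 1 list. The 38 lists with at least 3 genes past the filter were tested with camera from limma, with its preset inter-gene correlation of 0.01. Camera compares the members with all other genes. Under that preset it treats genes as nearly independent units, so its p-values do not measure the spread between tumours. The same test with an estimated correlation, and fry from limma, were run beside it. A list's score in a tumour is the mean log2(TPM + 1) of its members, and scores were compared by an exact two-sided permutation test over 20 assignments, whose smallest p is 0.1.

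The genes named are up to 12 per direction past the threshold with non-overlapping groups, filled to 5 by the smallest unadjusted p where fewer passed, up to 4 members of each list described by the smallest unadjusted p, and 26 genes fixed in advance. Predicted gene models were left out of the first part. Values of a few genes that this rule takes are not reported here. Any other gene is said to have been chosen after its values were seen.

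The fit was tested on simulated data for this comparison with 15023 genes, 200 of them changed, and independent noise between genes. It recovered 14.2% of genes changed 1.5-fold, 71.1% of those changed 2-fold and 96.2% of those changed 4-fold, all recovered genes with the right sign. In simulated lists of 15 genes with independent noise, a shift of 0.5 on the log2 scale was called in 100% of lists and an unshifted list in 0.455%. Members of real lists were correlated, with a median estimated correlation of 0.363 over the 38 lists, so this second check is optimistic for them. The first check gave every tumour the same spread, while FA replicate 3 stood apart in the real data. Its recovery rates may therefore not hold for this comparison.

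Alternatives covered pseudocounts of 0.1 and 0.5, no filter and a mean of at least 5 TPM, median-ratio rescaling, rescaling without mitochondrially encoded genes and the 50 highest genes, quantile normalization, no variance trend, array weights, the replicate number as a block, an adjusted p under 0.1, and leaving out each tumour in turn. Restricting the fit to 12895 protein-coding genes, and adding the skeletal muscle score as a covariate, were chosen after seeing the data. For the first of these, gene classes came from a mouse annotation that held 14919 of the 15023 identifiers. Figures were drawn with matplotlib 3.10.9.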

Results

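The study measured how oral FA changes the tumour microenvironment of a transplanted pancreatic cancer in mice, with natural killer T (NKT) cells and antitumour immunity as its stated subject. The transcriptomes of 3 tumours from FA-treated mice and 3 tumours from PBS-treated mice were compared. The number of reads per tumour is unknown, because the values are TPM. Keratin 19 (Krt19), a ductal epithelial marker, stood at 1246 ± 67.3 TPM in FA tumours and 1115 ± 61.6 TPM in PBS tumours (SD, n = 3 each), and the macrophage marker Adgre1 at 13.4 ± 4.66 and 11.0 ± 1.69 TPM. Transcripts of lymphocytes were scarce. Of 83 genes in the lists for T cells, cytotoxic lymphocytes, NK cells, NKT cells and B cells, 58 averaged under 1 TPM.

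The first question was whether FA changed single genes. None of the 15023 tested genes passed the threshold, so the genes named next are those with the smallest unadjusted p-values. Rsad2 (ENSMUSG00000020641), which encodes the antiviral protein viperin, stood at 3.08 ± 0.682 TPM in FA tumours and 1.41 ± 0.308 TPM in PBS tumours, a log2 difference of 0.76 ± 0.18. Irak2 (ENSMUSG00000060477), a kinase of interleukin-1 and Toll-like receptor signalling, stood at 44.2 ± 2.51 and 35.7 ± 0.234 TPM, a difference of 0.30 ± 0.07. Cish (ENSMUSG00000032578), a cytokine-induced inhibitor of STAT5 signalling, was lower in all 3 FA tumours, at 7.82 ± 0.338 against 11.7 ± 1.57 TPM, a difference of -0.52 ± 0.12. The collagen gene Col8a1 was at 49.1 ± 4.08 and 34.8 ± 5.29 TPM, and the circadian repressor Bhlhe41 at 13.9 ± 1.93 and 19.2 ± 1.53 TPM.

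The other genes with the smallest p-values were short or of few TPM. In the higher direction they were a 5S_rRNA copy, at 2.25 against 0.33 TPM, and the pseudogene Ndufs5-ps, at 12.4 ± 1.04 against 4.65 ± 2.57 TPM. In the lower direction they were the antisense gene Tmem147os, the microRNA gene Mir1902 and Ccdc136, with log2 differences of -0.73, -3.43 and -0.67. Reads of copies and pseudogenes can be shared with other genes, so the values of the 5S_rRNA copy and Ndufs5-ps are uncertain. The libraries were stranded, but whether the strand was kept in processing is not given, so Tmem147os could share reads as well. Mir1902 ranged from 4.76 to 54.16 TPM within the PBS tumours alone.

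By limma, 0 genes were higher and 0 genes were lower in FA at an adjusted p under 0.05, and 192 genes had an unadjusted p under 0.05, of which 103 were higher and 89 lower, where chance gives about 751. The smallest adjusted p was 0.218, for ENSMUSG00002075890, a gene without a symbol chosen here after its values were seen, at 4.60 ± 0.501 TPM in FA tumours and 0.17 ± 0.269 TPM in PBS tumours. The FA and PBS values did not overlap for 705 genes, which is 4.69% where chance gives 10%.

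Interferon-response genes rose as groups under the preset correlation. All 23 measured members of the type I interferon list had a higher mean in FA tumours, with a mean log2 difference of 0.41 ± 0.24 (adjusted p = 2.15e-11, camera). With an estimated correlation its adjusted p = 0.686, so the call did not hold. Mx2, an antiviral GTPase, stood at 3.23 ± 1.00 TPM in FA and 1.78 ± 0.439 TPM in PBS tumours, Ifit2 at 4.34 ± 0.492 and 3.10 ± 0.506 TPM, and Cmpk2 at 2.52 ± 1.11 and 1.21 ± 0.367 TPM. In the interferon gamma list 18 of 19 measured members had a higher mean, by 0.35 ± 0.15 on average (adjusted p = 1.29e-09), and this list too had an adjusted p = 0.686 with an estimated correlation. The chemokine gene Cxcl10 was at 9.85 ± 4.88 and 4.56 ± 1.57 TPM, and the guanylate-binding protein genes Gbp2 at 9.33 ± 0.934 and 6.26 ± 1.31 TPM and Gbp7 at 4.90 ± 0.357 and 3.48 ± 0.82 TPM.

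Unadjusted p-values under 0.05 were found for 6 members of the type I list and 4 of the interferon gamma list, and 0 members of either list passed when adjusted over the list alone. Type I scores were 3.31, 3.22 and 3.20 in the FA tumours and 2.99, 3.14 and 2.36 in the PBS tumours, with an exact permutation p of 0.1, the smallest that 3 against 3 allows (adjusted p = 0.844). Scores of the 2 groups did not overlap for 2 of 38 lists, this one and skin epithelium, where chance gives 10% of lists. Without PBS replicate 3 the type I difference was 0.18. The interferon gamma scores of the groups overlapped, at 2.61, 2.85 and 2.84 in FA and 2.64, 2.41 and 2.19 in PBS tumours (exact permutation p = 0.2). Interferon gamma itself (Ifng) was listed at 0 in 5 of 6 tumours, and Cxcl9 was at 0.693 ± 0.182 and 0.463 ± 0.528 TPM.

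**Figure D1:**
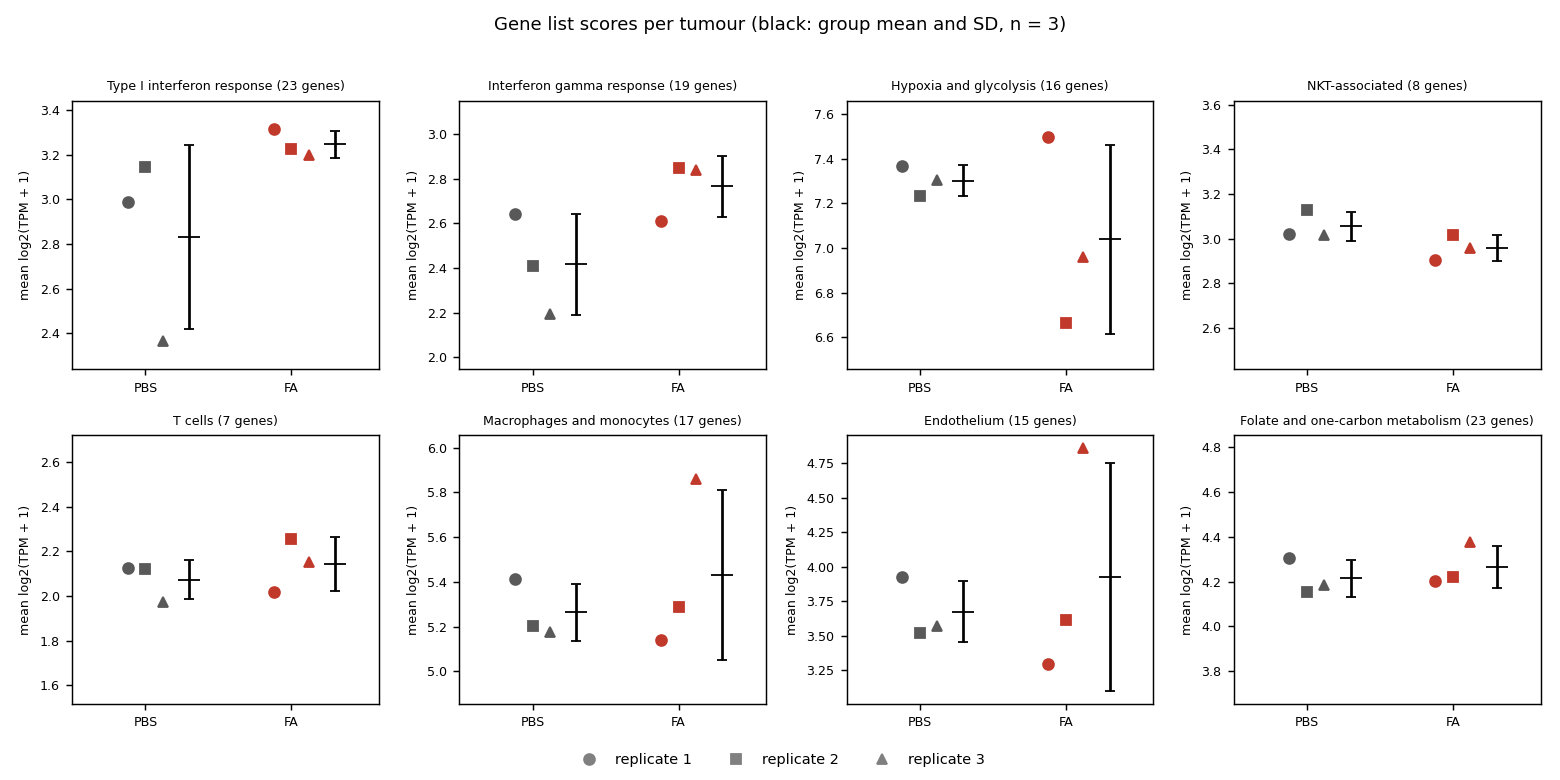
Scores of 8 gene lists per tumour, as the mean log2(TPM + 1) of the list's genes (vertical axis), by treatment (horizontal axis). Symbols are single tumours and black bars are the mean and SD of 3 tumours. Type I interferon scores lie between 3.20 and 3.31 in FA tumours and between 2.36 and 3.14 in PBS tumours, while FA replicate 3 lies above all others for endothelium at 4.87.

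NKT cells, the study's subject, left few transcripts in whole-tumour RNA, and 3 of their markers averaged under 1 TPM and were not among the genes tested. The NKT lineage factor Zbtb16 was at 0.113 ± 0.127 TPM in FA and 0.0867 ± 0.0379 TPM in PBS tumours, the receptor gene Klrb1c at 0.343 ± 0.232 and 0.287 ± 0.0351 TPM, and the homing receptor gene Cxcr6 at 0.397 ± 0.197 and 0.213 ± 0.0513 TPM. Cd1d1 (ENSMUSG00000028076), which encodes the molecule that presents lipids to NKT cells, was at 8.22 ± 0.987 and 8.26 ± 1.10 TPM, with an interval of the log2 difference from -0.34 to 0.33. Cxcl16, the ligand gene of Cxcr6, was at 76.4 ± 5.67 and 72.3 ± 6.99 TPM. The NKT-associated list, with 8 of 20 members past the filter, differed by -0.10 ± 0.05 (adjusted p = 0.46, camera). Leaving out 1 tumour gave differences from -0.12 to -0.03, the last without PBS replicate 2, and no call.

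Conventional lymphocyte genes were as sparse. Cd3e was at 0.29 ± 0.227 TPM in FA and 0.147 ± 0.0231 TPM in PBS tumours, Cd4 at 0.89 ± 0.624 and 0.617 ± 0.366, Cd8a at 0.0767 ± 0.0666 and 0.0333 ± 0.0306, Foxp3 at 0.40 ± 0.154 and 0.35 ± 0.0458, and the NK receptor gene Ncr1 at 0.137 ± 0.119 and 0.183 ± 0.127. The cytotoxic genes Gzmb and Prf1 were at 1.12 ± 1.22 and 0.67 ± 0.725 TPM in FA tumours and at 1.40 ± 1.37 and 0.943 ± 0.919 TPM in PBS tumours. Within the T cell list the log2 difference was -0.33 for Trbc2 and 0.41 for Trac, with unadjusted p-values of 0.0483 and 0.0886 from limma. The lists for T cells (0.07 ± 0.09), cytotoxic lymphocytes (0.12 ± 0.23), NK cells (0.10 ± 0.18), regulatory T cells (0.09 ± 0.09) and plasma cells (0.09 ± 0.35) did not pass. They rest on 7, 3, 6, 6 and 5 measured genes, and the mean of the cytotoxic list was above 0 while its median was -0.02. The B cell list was not tested, with 1 of 15 genes past the filter.

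Folate enzymes and carriers showed no difference past the threshold. Thymidylate synthase (Tyms) was at 60.5 ± 10.1 TPM in FA and 61.5 ± 11.6 TPM in PBS tumours, Mthfd2 at 37.9 ± 14.1 and 30.0 ± 3.72, and Shmt2 at 94.9 ± 17.2 and 86.4 ± 7.02. The reduced folate carrier gene Slc19a1 differed by 0.09 in log2, with an interval from -0.17 to 0.34, and the proton-coupled carrier gene Slc46a1 by -0.10, with an interval from -0.39 to 0.19. Folr2, a folate receptor gene of macrophages, was at 19.8 ± 9.07 and 15.3 ± 5.18 TPM. The folate and one-carbon list, with 23 of 25 genes past the filter, differed by 0.05 ± 0.07 (adjusted p = 0.185, camera). Purine and pyrimidine synthesis (0.02 ± 0.08), serine and methionine metabolism (0.04 ± 0.07) and the cell cycle (0.05 ± 0.11) did not pass either. The cell cycle list was called higher without FA replicate 2 (0.11, adjusted p = 0.000152) and without PBS replicate 1 (0.12, adjusted p = 0.00023) under the preset correlation. Mki67, a proliferation marker, was at 37.4 ± 2.44 and 35.8 ± 4.86 TPM.

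Hypoxia and glycolysis genes fell as a group under the preset correlation. All 16 members had a lower mean in FA tumours, by -0.26 ± 0.25 on average (adjusted p = 4.09e-05, camera), and none had an unadjusted p under 0.05. With an estimated correlation the adjusted p = 0.686. Vegfa was at 149 ± 41.1 TPM in FA and 183 ± 2.61 TPM in PBS tumours, Bnip3 at 112 ± 57.7 and 148 ± 12.1, and Car9 at 51.3 ± 29.7 and 72.6 ± 12.1. The scores were 7.50, 6.66 and 6.96 in FA tumours and 7.37, 7.23 and 7.31 in PBS tumours, so FA replicate 1 was the highest of all 6. Without FA replicate 2 the difference was -0.07 and was not called, and without FA replicate 1 it was -0.49. The list for nerve and Schwann cells, with 5 measured genes led by S100b (13.2 ± 3.29 and 19.5 ± 4.73 TPM), fell by 0.38 ± 0.32 under the preset correlation (adjusted p = 0.0212) and lost its call with an estimated correlation (adjusted p = 0.686). It also lost it without FA replicate 1, FA replicate 2 or PBS replicate 2, at -0.38, -0.20 and -0.18.

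Myeloid, stromal and muscle genes were higher on average in FA tumours, and FA replicate 3 held the highest value for most of them. The macrophage and monocyte list rose by 0.17 ± 0.23, the alternatively activated macrophage list by 0.23 ± 0.28, neutrophils by 0.28 ± 0.35, dendritic cells by 0.20 ± 0.24, fibroblasts by 0.20 ± 0.39, extracellular matrix by 0.22 ± 0.38 and endothelium by 0.25 ± 0.50, all under the preset correlation, with adjusted p-values from 0.00964 to 0.0479. With an estimated correlation each of these lists had an adjusted p = 0.686. Col1a1, the main fibrillar collagen gene, was at 451 and 574 TPM in 2 FA tumours, at 1680 TPM in FA replicate 3, and between 378 and 808 TPM in PBS tumours. The endothelial receptor gene Kdr was at 17.4 TPM in FA replicate 3 and between 4.00 and 7.69 TPM in the other 5 tumours. The neutrophil gene S100a8 was at 8.86 ± 5.17 TPM in FA and 5.71 ± 0.428 TPM in PBS tumours. Skeletal muscle genes had the largest list difference, 0.88 ± 1.86 (adjusted p = 0.0195, and adjusted p = 0.686 with an estimated correlation), with Tnni2 at 121 TPM in FA replicate 3 and between 10.6 and 27.6 TPM elsewhere.

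Without FA replicate 3 the differences were -0.048 for macrophages, 0.020 for alternatively activated macrophages, -0.043 for neutrophils, -0.028 for dendritic cells, -0.16 for fibroblasts, -0.10 for extracellular matrix, -0.22 for endothelium and -0.56 for skeletal muscle. Endothelium and fibroblasts were then called in the lower direction, with adjusted p-values of 0.000129 and 0.00544 under the preset correlation. Calls also ended without PBS replicate 2 for macrophages (0.14), neutrophils (0.18), dendritic cells (0.17), fibroblasts (0.17), extracellular matrix (0.030), endothelium (0.17) and skeletal muscle (0.020), and without PBS replicate 3 for alternatively activated macrophages (0.06), fibroblasts (0.09) and endothelium (0.20). FA replicate 3 also stood apart over all genes. Its correlation with the other tumours across genes, which are not independent replicates, was between 0.949 and 0.968, against 0.981 to 0.987 among the other 5, and it had the highest score in 25 of 38 lists.

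The remaining lists past the threshold under the preset correlation were MHC class I presentation (0.20 ± 0.26), immune checkpoints (0.22 ± 0.17), mitochondrially encoded genes (0.13 ± 0.07), mast cells and eosinophils (0.31 ± 0.34), skin epithelium (0.30 ± 0.15), epithelial tumour cells (0.10 ± 0.22), chemokines (0.14 ± 0.32) and lymphoid stroma (0.30 ± 0.26), all higher in FA, and each had an adjusted p = 0.686 with an estimated correlation. Without FA replicate 3 none of these was called, at -0.036, 0.040, 0.093, 0.14, 0.17, 0.028, -0.14 and 0.10 in the same order. Other single tumours also ended calls, namely PBS replicate 3 for MHC class I (0.09), skin epithelium (0.22), epithelial tumour cells (-0.022), chemokines (0.11) and lymphoid stroma (0.16), PBS replicate 2 for mast cells (0.27) and chemokines (0.037), PBS replicate 1 for mast cells (0.29), epithelial tumour cells (0.014) and lymphoid stroma (0.37), FA replicate 2 for mast cells (0.14), skin epithelium (0.33) and epithelial tumour cells (0.12), and FA replicate 1 for skin epithelium (0.38) and lymphoid stroma (0.31). The peptide transporter gene Tap1 was at 7.93 ± 4.42 TPM in FA and 5.40 ± 1.80 TPM in PBS tumours, the mast cell protease gene Cpa3 at 9.39 ± 5.45 and 6.02 ± 0.837, and the chemokine genes Ccl5 at 7.73 ± 1.48 and 5.10 ± 1.65 and Ccl20 at 8.75 ± 1.12 and 6.73 ± 0.66. Lists that did not pass were MHC class II presentation (0.16 ± 0.29), cytokines (0.14 ± 0.23), the mesenchymal programme (0.11 ± 0.28), adipocytes (0.30 ± 0.63), erythroid cells (0.37 ± 0.83) and cytosolic ribosomal proteins (-0.02 ± 0.04). Neither did amino acid stress, with a mean of -0.01 and a median of 0.03, nor immediate early genes, with a mean of -0.03 and a median of 0.01. Leaving out single tumours gave some of these a call under the preset correlation, namely erythroid cells without PBS replicate 3 (1.35, adjusted p = 4.02e-14), adipocytes and MHC class II without FA replicate 1 (0.84 and 0.38) or PBS replicate 2 (0.58 and 0.19), the mesenchymal programme and, in the lower direction, ribosomal proteins without FA replicate 2 (0.20 and -0.043) or PBS replicate 1 (0.22 and -0.046), and immediate early genes, lower, without FA replicate 3 (-0.13).

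**Figure D2:**
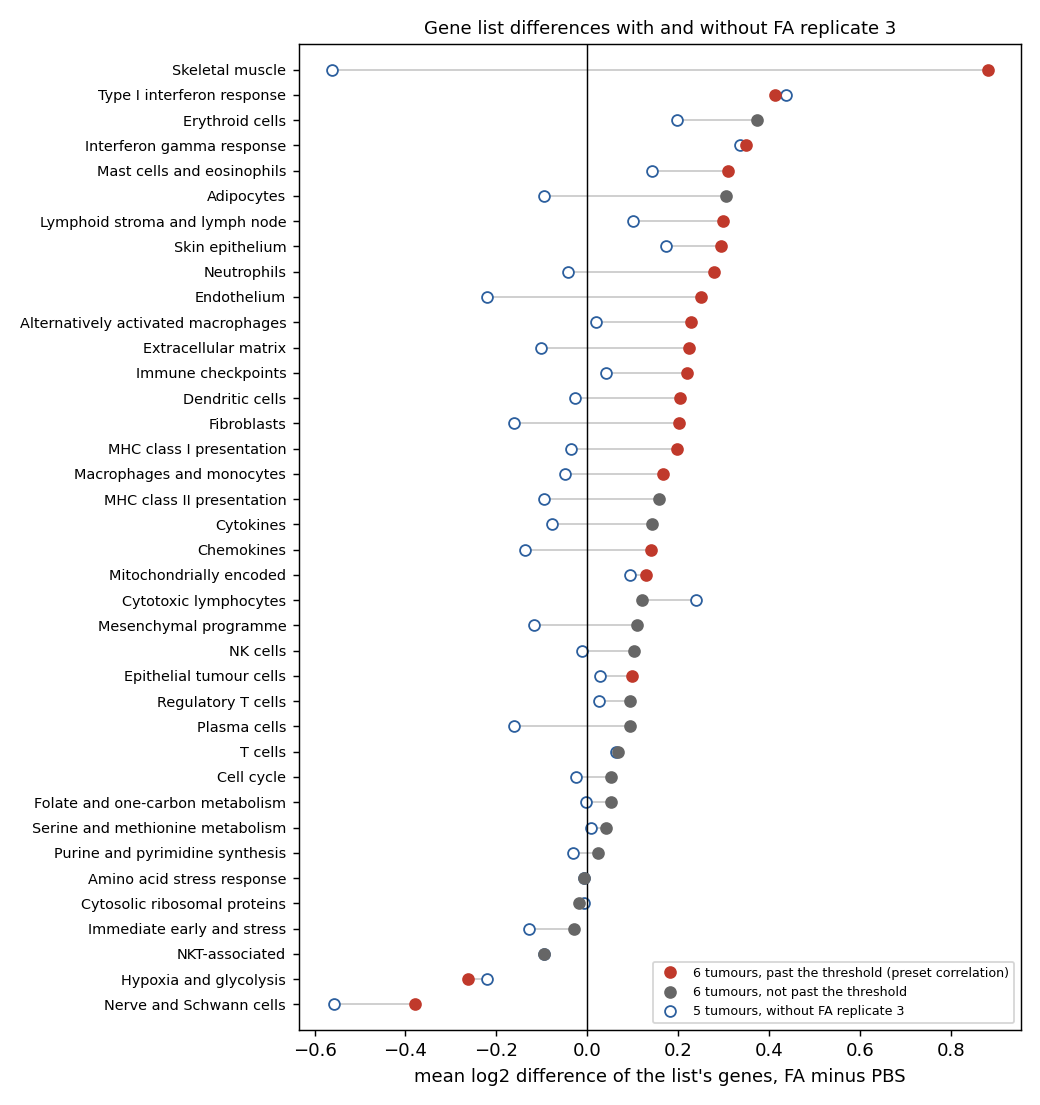
Mean log2 difference of each tested gene list, FA minus PBS (horizontal axis), for 38 lists (vertical axis). Filled points use all 6 tumours, in red where the list passed the threshold under the preset correlation, and open points leave out FA replicate 3. The type I interferon list moves from 0.41 to 0.44 and the interferon gamma list from 0.35 to 0.33, while endothelium moves from 0.25 to -0.22 and skeletal muscle from 0.88 to -0.56.

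Over all 38 lists, 18 were higher and 2 lower in FA under the preset correlation, and 0 were called with an estimated correlation or by fry, with 1 list at an unadjusted p under 0.05 by each. The smallest adjusted p was 0.686 with the estimated correlation and 0.776 by fry, and 0.87 by fry for changes in either direction. Without FA replicate 3, 4 of the 20 called lists were called in the same direction, namely both interferon lists, hypoxia and glycolysis, and nerve and Schwann cells.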

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

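The protein-coding restriction and the skeletal muscle covariate were chosen after seeing the data, as were the genes named in this part that are not in the main results. By limma, the counts of 0 genes higher and 0 lower in FA stayed at 0 in every alternative but 2, also at an adjusted p under 0.1. Without the filter 2 short genes were higher (Gm24045 and Gm22728), and leaving out 1 tumour gave 0 to 1 lower gene, the 1 being Snord14d without FA replicate 3. None of the named genes passed in any alternative. The median difference of all genes stayed under 0.02 in size throughout. TPM holds no depth, so what depth limits cannot be told.

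The 18 higher and 2 lower lists became 8 and 1 without the filter and 4 and 3 with array weights. With a mean of at least 5 TPM, 1 list was lower. An estimated correlation gave 0 and 0 lists, and so did fry with 0 and 0. The muscle covariate left 5 higher. Leaving out 1 tumour gave 2 to 18 higher and 1 to 5 lower lists, with 2 and 5 without FA replicate 3. The higher count was 11 without PBS replicate 2 and 11 without PBS replicate 3. Apart from the estimated correlation and fry, both interferon lists were called higher in all 19 settings, the reported one included, with differences from 0.18 to 0.57 for type I and from 0.24 to 0.48 for interferon gamma.

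Array weights turned the means of chemokines (-0.082), fibroblasts (-0.042), extracellular matrix (-0.065), endothelium (-0.084) and skeletal muscle (-0.32) below 0. Leaving out 1 tumour gave ranges that cross 0 for macrophages (-0.048 to 0.31), neutrophils (-0.043 to 0.52), dendritic cells (-0.028 to 0.33), MHC class I (-0.036 to 0.33), chemokines (-0.14 to 0.31), fibroblasts (-0.16 to 0.40), extracellular matrix (-0.10 to 0.42), endothelium (-0.22 to 0.57) and skeletal muscle (-0.56 to 2.22), each lowest without FA replicate 3, and for epithelial tumour cells (-0.022 to 0.31), lowest without PBS replicate 3. For array weights the cause was not tested. The cell cycle list gained a call with quantile normalization and with a mean of at least 5 TPM, and the T cell list without the filter. Immediate early genes gained one in the lower direction with array weights (-0.16, adjusted p = 0.0314, camera with the preset correlation). Over all lists and alternatives, 593 values kept their side of the threshold or moved within their spread. A further 126 lost the call, 17 gained one, and 3 moved beyond their spread without a call. Another 15 changed sign in lists called in the reported setting or in the alternative. Changes of sign in lists called in neither were not counted apart, and fall among the 593 or the 3. Lists left with under 3 genes gave no value.

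The labels do not say that replicate numbers pair the tumours, and the values gave no sign of pairing. With 3 tumours per group they cannot exclude it. Deviations of same-numbered tumours correlated at -0.21, 0.05 and -0.02 across genes, and FA replicate 1 correlated best with PBS replicate 2, at 0.20. The highest value was 0.24, between FA replicate 3 and PBS replicate 1. With the replicate number as a block there were 0 higher and 0 lower genes and 18 higher and 2 lower lists.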

Other observations

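The tests of explanations in this part were chosen after the values they concern had been seen, while the list calls and the leaving out of each tumour that they draw on were planned. The genes named here were chosen after their values were seen.

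Several gene groups varied widely between tumours within both treatment groups. The granzyme genes Gzmc, Gzmd, Gzmf and Gzmg, near-identical neighbours whose reads can be shared in counting, were all lowest in FA replicate 3 and PBS replicate 1. Gzmf was at 6.14, 18.23 and 0 TPM in the FA tumours and at 0.05, 9.50 and 26.89 TPM in the PBS tumours. Gzmc followed at 7.84, 19.69, 2.13, 2.95, 15.28 and 26.74 TPM in the same order, while Gzme stayed between 7.88 and 20.06 TPM. The group means of Gzmf, 8.12 ± 9.28 TPM in FA and 12.1 ± 13.6 TPM in PBS tumours (SD, n = 3 each), differed by less than the spread within each group.

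Gastric-type epithelial genes varied between tumours to unlike degrees. The ratio of the highest to the lowest tumour was 21.0 for Gkn1 and 19.4 for Gkn2. It was 4.41 for the trefoil factor gene Tff1, 5.29 for Tff2 and 6.09 for Muc5ac. The gastrokine genes Gkn1 and Gkn2, secreted by normal stomach epithelium, were at 32.96, 118.8 and 502.1 TPM and at 41.6, 159.6 and 588.8 TPM in the FA tumours, against 62.2, 227.1 and 23.9 TPM and 90.4, 338.4 and 30.4 TPM in the PBS tumours. Tff2 and Muc5ac, a trefoil factor and a gastric mucin, were instead highest in PBS replicate 2, at 254.7 and 14.7 TPM, against at most 65.5 and 5.90 TPM elsewhere. Within the FA tumours they varied little, from 49.3 to 65.5 TPM and from 3.67 to 5.90 TPM. The keratin genes Krt8 and Krt18 varied by 1.32-fold and 1.16-fold over the same tumours, the ratio of the highest to the lowest. Immunoglobulin transcripts were patchy, with Igkc at 40.3 TPM in FA replicate 3, 19.7 TPM in PBS replicate 2 and at most 4.80 TPM in the other tumours. The acute-phase gene Saa3 was at 299.9 TPM in FA replicate 3 and between 6.89 and 65.6 TPM elsewhere.

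FA replicate 3 stood apart from the other 5 tumours, with 192 genes over 2-fold above and 107 genes over 2-fold below all of them, 20 of these over 4-fold below. Genes far lower there included Pzp (0.10 TPM against 15.2 to 29.6), Aadac (0.73 against 20.4 to 34.3), Cym (0.60 against 18.7 to 33.3) and Lcn2 (11.3 against 59.1 to 156.2), and Spp1 was at 6930 TPM against at least 11246. Muscle tissue in the sample is a candidate source of the muscle transcripts. There, 14 of 14 tested skeletal muscle genes were highest, with Acta1 at 385 and Ckm at 195 TPM. Acta1 was also at 46.2, 49.5 and 43.4 TPM in FA replicate 2, PBS replicate 1 and PBS replicate 3. It was at 0.07 and 0 TPM in FA replicate 1 and PBS replicate 2. Dilution by muscle tissue alone, with cancer cells in an unchanged state, is argued against for the lowered genes, because it would lower genes of those cells alike. The median deviation of the epithelial list was 0.26 (quartiles -0.41 and 0.75). Those 20 genes, picked for being low, deviated by -2.29 or lower, and Lcn2 belongs to both sets. Dilution together with a changed state of the cancer cells cannot be judged from this. Genes of host cell types did not rise alike, as endothelial genes deviated by 0.82 more than macrophage genes in log2. The first quartile of one (0.99) lay above the third quartile of the other (0.87). This cannot tell whether the share of tumour cells was smaller, because such a share need not raise every host cell type alike. What stays open is a tumour with more vessels and stroma, a smaller share of tumour cells, a different state of its cancer cells, or several of these together. The design gives no biological group for this tumour beyond FA.

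Sex-linked genes moved with the same tumour. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were at 2.13, 2.38, 2.12 and 1.99 times the mean of the other 5 tumours in FA replicate 3, while Xist was at 0.497 times that mean, at 113.8 TPM. A larger share of male host cells may account for the Y-linked part, as a hypothesis, because their score followed the endothelium score over the 6 tumours (Pearson r = 0.984, exact permutation p = 0.00556, adjusted 0.0111; Spearman rho = 0.943, exact permutation p = 0.0167, adjusted 0.0333; 4 relations computed), although r was 0.649 without the 2 tumours farthest from the median. It followed the skeletal muscle score as well (r = 0.879, exact permutation p = 0.00278, adjusted 0.0111; rho = 0.943), and FA replicate 3 weighs on every relation, so the kind of host cell stays open. The epithelial list cannot tell whether a smaller share of tumour cells was the whole cause of the lower Xist. Its median deviation lay 1.27 above the log2 ratio of Xist, a little more than the width between the quartiles of its genes (-0.41 to 0.75). Of its 17 genes, 6 were lower in that tumour. A different state of the cancer cells, left open above, could hold such genes up at a smaller share. Cldn4, a member, was at 6.88 TPM there and at most 2.17 TPM elsewhere. A smaller share of tumour cells, as a part or the whole of the cause, stays open. Xist ran against the endothelium score (r = -0.928, adjusted p = 0.0472; rho = -0.714, adjusted p = 0.181) and the Y-linked score (r = -0.890, adjusted p = 0.0472; rho = -0.6, adjusted p = 0.242), by exact permutation. The sex of the mice and of the line was not used here.

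The higher type I interferon list in FA could rest mostly on 1 tumour. FA replicate 3 is argued against, because without it the type I difference was 0.44 ± 0.24. A larger share of macrophages is argued against only without that tumour, where their list differed by -0.048 ± 0.11. With all 6 tumours the macrophage list differed by 0.17 ± 0.23, so a part played by macrophages stays open there. PBS replicate 3 may supply most of the type I difference, which was 0.18 without it, with an adjusted p of 0.000311 (camera), the highest over the 6 tumours left out in turn under the preset correlation. The interferon gamma list kept 0.24 of its difference of 0.35 without PBS replicate 3 (adjusted p = 7.6e-06, camera with the preset correlation), so most of that difference does not come from this tumour. With an estimated correlation neither interferon list was called in the 6 tumours (adjusted p = 0.686 for each, camera). An effect of FA on interferon-response genes stays open as a hypothesis, and so does a low interferon state of 1 PBS tumour. Whatever the prefix shared by each group's sample descriptions marks cannot be separated from treatment here either.

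The 6 tumours allow 10 splits into 3 and 3, too few for a share under 0.05. Under the preset correlation of camera, the real split called 20 lists and the highest other split called 20. Of the 10 splits, 3 called at least 20 lists, with the real split among these 3. The smallest adjusted p of a list by that test was 2.15e-11 in the real split, and 4 other splits had a smaller one, down to 1.21e-13. With an estimated correlation no split called a list, the real one included. The groups differed in the type I list by 0.41 in the real split and by at most 0.38 in another. For genes, the real split called 0 and the highest other split called 4, and a real count of 0 makes this comparison uninformative. The real split had 192 genes at an unadjusted p under 0.05 and the other splits 205 to 1173, where chance gives about 751.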
